A study of Homo sapiens with 39 samples.

How the data were processed

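Gene expression was measured on Affymetrix PrimeView arrays in 7 human acute myeloid leukemia cell lines treated with tamibarotene (SY-1425) or with its DMSO vehicle for 24 h. The labels state that the drug was added at 100 nM for a final concentration of 50 nM. The 39 arrays comprise 21 tamibarotene arrays, 3 in each line, and 18 vehicle arrays, 3 in each line except Kasumi-1, KG-1a and Sig-M5, which have 2. Nothing in the labels says that the replicates are separate cultures, so the p-values rest on the spread between these samples. That spread is pooled over all 14 groups of line and arm and is not that of a line's own arrays.

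The deposited values are normalized intensities on the log2 scale, made with RMA in the affy package per the submitters' processing notes, which name no version. The values ran from 1.68 to 14.43, the array medians from 5.01 to 5.17 and the array standard deviations from 2.31 to 2.49. No further normalization was applied. The notes do not say whether all arrays were normalized together. The highest correlation between 2 arrays of the same group was 0.9976, so no array was a copy of another. The value table holds 49395 probe sets. Gene symbols are those of the platform annotation, and members of the gene lists with older symbols were matched through a RefSeq gene table of assembly GRCh38.p14, which was used for names only. 44988 probe sets named 1 gene symbol, 1832 named several and 2473 named none, and 102 were control probe sets. Each of the 18132 genes tested was represented by its probe set with the highest mean over all 39 arrays, and 11734 genes had more than 1 probe set to choose from. Probe sets with no symbol or several were left out of the gene tests. No genomic positions are given, because the values name no genome build.

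All arrays entered a single linear model with a mean for each of the 14 groups of line and arm, fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust; 25 residual degrees of freedom). Tables were handled with the data.table package (version 1.17.8), and plots were drawn with Python 3.11.15 and matplotlib 3.10.9. The contrasts were tamibarotene minus vehicle in each line, the unweighted mean of the 7 differences, and a moderated F test with 6 degrees of freedom of the differences between the lines' responses. For a named gene, a line's response was also set against the mean response of the other 6 lines. P-values were adjusted by Benjamini-Hochberg over all genes of a contrast, and a gene was called at an adjusted p under 0.05 with no minimum fold. Errors are the standard errors of the fit unless named otherwise. The number of arrays limits the precision of every value.

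31 gene lists were written from textbook knowledge and tested with camera at a preset correlation of 0.01 in the 7 lines and the average, with adjustment over the 248 tests, and again with an estimated correlation and with fry. The lists hold retinoic acid-induced genes, retinoid metabolism, blood cell type markers, granule proteins, antigen presentation, interferon, cytokine, cell cycle, stress, lipid, chromatin, HOX and reference genes, and markers of adherent cells. For each list, the counts of called members are given over all genes and adjusted over the list alone. The relation of the RARA level in vehicle arrays to the response was tested over the 7 lines with a two-sided exact permutation test over all 5040 pairings for 4 measures of response. Overlaps of calls between the 21 pairs of lines were tested in each direction with a one-sided Fisher's exact test, adjusted over the 42 tests.

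The genes named in the text follow a rule. For each line these are the 6 largest rises and 6 largest falls among called genes whose treated and vehicle arrays did not overlap, and for the average the 12 largest rises and 8 largest falls with the same sign in all 7 lines. The 10 genes with the smallest p of the F test, up to 4 called members of each list with the smallest adjusted p in each contrast, and RARA, RARB, RARG, RXRA, RXRB, CYP26A1, DHRS3, CD38, ITGAM and MYC complete the rule. Samples, lists, this rule and the planned tests and alternatives were fixed before the data were examined. The tests and alternatives stated to be chosen later, and the naming of MYADM and ANXA2, were not.

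RNA integrity was read from the array's own control probe sets, as the 3' minus the 5' log2 value of beta-actin and of GAPDH, where a larger difference goes with more degraded RNA. Replicate numbers are shared between arms of a line, so the correlation of the deviations of same-numbered arrays from their group means was checked. Every such correlation was above 0.1 in OCI-M1 alone, where they ran from 0.118 to 0.371, and the pairing there comes from the data and not from the labels. Elsewhere they were uneven, up to 0.67 in MV-4-11, 0.572 in NOMO-1 and 0.461 in OCI-AML3. Of 18 same-numbered pairs over all lines, 12 were the best match of their treated array. With 3 vehicle arrays to choose from, these were 3 of 3 in NOMO-1 and OCI-M1 and 2 of 3 in MV-4-11 and OCI-AML3. In Kasumi-1, KG-1a and Sig-M5, the correlations of a treated array with the 2 vehicle arrays are equal and opposite. A match there says little. Pairing in NOMO-1, MV-4-11 and OCI-AML3 is therefore possible, and it is not excluded elsewhere. The main fit uses no block in any line. The fit with the replicate number as a block called 228 genes in OCI-M1 against 197 without it, and 1002 in NOMO-1 against 631.

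The alternatives tried were quantile normalization, centring each array on its median, limma's trend and robust options, array weights, leaving out the 40% dimmest genes, the mean of all probe sets of a gene, every probe set tested singly, each line fitted alone, the replicate block, an adjusted p under 0.01, a minimum log2 fold change of 1, and leaving out each array and each line in turn. The adjusted p under 0.01, the minimum log2 fold change of 1 and the test of every probe set were applied to counts only, not to single named genes. Array weights were used although limma warned that their estimation had not converged. The highest weight, 10.13, went to OCI-AML3 vehicle replicate 1. The beta-actin 3' minus 5' difference as a covariate was chosen after seeing the data. So was the removal of Kasumi-1 tamibarotene replicate 1 together with vehicle replicate 2, and of the lines Kasumi-1 and Sig-M5 together. Of the 2 removed arrays only vehicle replicate 2 had a high actin difference, at 1.18 against 0.22.

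The procedure was tested on simulated data for the 18132 genes, with 200 genes changed in each line. At a log2 change of 0.5, from 32.8% to 58.2% of the changed genes were recovered across the 7 line contrasts, at 1 from 89.6% to 98.5%, and at 2 from 97% to 100%. False calls made up 4.2% to 7.01% of the calls of a line. The average contrast recovered 196 of 200 genes raised by 0.5 in every line and called 38 of 16555 unchanged genes. The test between lines recovered 448 of 462 genes changed by 2 in 1 line and called 51 of 16555 unchanged genes. Camera called the list that was raised and 0 of the 30 lists that were not. The simulated noise was independent between genes and had the same spread on every array, with no degraded array. These rates therefore need not hold for the measured arrays.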

Results

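The study measured mRNA levels in 7 human acute myeloid leukemia lines after 24 h with tamibarotene, a synthetic agonist of the retinoic acid receptor alpha (RARA), or with vehicle. Kasumi-1, MV-4-11, NOMO-1, KG-1a, OCI-AML3, OCI-M1 and Sig-M5 each had 3 tamibarotene arrays. MV-4-11, NOMO-1, OCI-AML3 and OCI-M1 had 3 vehicle arrays, and Kasumi-1, KG-1a and Sig-M5 had 2. The array medians lay between 5.01 and 5.17 on the log2 scale. Changes are log2 fold changes, tamibarotene minus vehicle, each with its standard error (SE) from limma, and adjusted p-values are those of limma for a gene and of camera for a list unless another test is named.

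RNA integrity was read from the control probe sets on each array. The beta-actin 3' value exceeded the 5' value by 0.81 and 1.89 in Sig-M5 vehicle replicates 1 and 2, against 0.31 to 0.34 in the treated Sig-M5 arrays. In Kasumi-1 the difference was 1.18 in vehicle replicate 2 and 0.30 in vehicle replicate 3, against 0.20 to 0.22 in the treated arrays. The other 36 arrays ranged from -0.02 to 0.56, and the highest of them were OCI-M1 vehicle replicates 2 and 3 at 0.52 and 0.56, against 0.11 in vehicle replicate 1 and 0.10 to 0.24 in the treated OCI-M1 arrays. The GAPDH difference was 0.40 and 1.07 in the Sig-M5 vehicle arrays and 0.37 in Kasumi-1 vehicle replicate 2, against -0.22 to 0.17 elsewhere, OCI-M1 included.

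**Figure D1:**
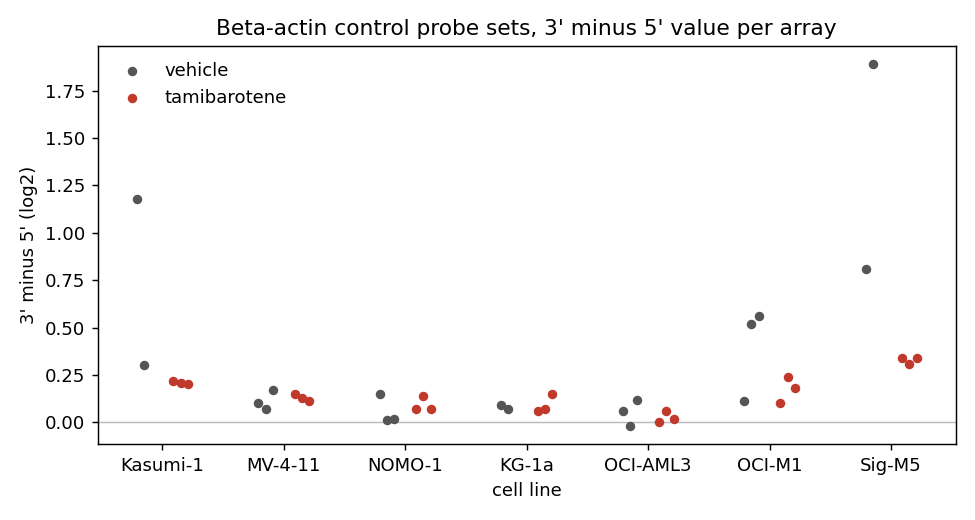
Beta-actin 3' minus 5' control value (log2) on each array, by cell line and arm, with a point for each array. Sig-M5 vehicle replicates at 0.81 and 1.89 and Kasumi-1 vehicle replicate 2 at 1.18 lie above the range of the other 36 arrays, whose highest value is 0.56.

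The average over the 7 lines addresses which genes change under the drug in the mean of the lines, to which a single line can contribute most of a change. Its SE and p-values rest on the spread between arrays within the groups and leave out the spread between lines. They therefore hold for these 7 lines only. CD38, an ectoenzyme on the surface of maturing myeloid cells and a known retinoic acid target, rose by 3.53 ± 0.05 (11.6-fold, adjusted p = 2.31e-30) and was called up in all 7 lines. Its change in a line ran from 0.92 in OCI-M1 to 7.18 in MV-4-11. DHRS3, a retinaldehyde reductase, rose by 3.92 ± 0.07 on average (15.1-fold, adjusted p = 3.87e-28). By its other probe sets its change in a line ran from 0.64 in Kasumi-1 to 5.57 in OCI-AML3 and from 0.11 in KG-1a to 1.89 in OCI-AML3. Among the genes with the same sign in all 7 lines, the other large rises were those of CLIC3 (2.73), the fructose transporter SLC2A5 (2.56), PLAAT4 (2.14), ITGAM, the integrin CD11b of mature myeloid cells (1.96), and ID1, an inhibitor of basic helix-loop-helix factors (1.77). They were followed by IL31RA (1.48), LRG1 (1.38), FBP1 (1.28), MAN1A1 (1.26) and P2RX5 (1.25). By its other probe sets the change of ITGAM in a line ran from 0.24 in Kasumi-1 to 2.89 in MV-4-11 and from 0.05 in OCI-M1 to 1.39 in Sig-M5. The largest falls were those of NIBAN1 (-0.99), CST7 (-0.97), the granule protease CTSG (-0.95), TENT5C (-0.89), MCUB (-0.87), the galectin LGALS3 (-0.84), TBL1X (-0.83) and the transcription factor BCL11A (-0.81). The SE of these 20 genes ran from 0.04 to 0.10, and they were called under every alternative applied to single genes. The falls named here were all smaller than the minimum log2 fold change of 1, which was applied to counts only.

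Of 18132 genes, 1216 rose and 2244 fell on average. The sign was the same in all 7 lines for 130 of the rises and 347 of the falls. The rise was at least 2-fold for 50 genes and the fall for 1 gene. CD38, ID1, MYADM and PLAAT4 were called up in each of the 7 lines separately, 17 genes in at least 6 lines and 47 in at least 5, while only ANXA2 and LGALS3 were called down in as many as 5. MYADM and ANXA2 were named after their values were seen. The average count was 2221 without Sig-M5 (961 rises and 1260 falls), 2306 with the actin difference as a covariate (957 and 1349) and 2458 without Kasumi-1 and Sig-M5 (1186 and 1272), and with every probe set tested 3909 probe sets rose and 4442 fell, so the excess of falls was smaller in each of these.

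Among 23 measured genes reported to be induced by retinoic acid, 12 rose, 2 fell and 9 did not pass the test on average (15 and 3 adjusted over the list alone). DHRS3, CD38, PLAAT4 and CYP26A1, the retinoic acid hydroxylase (2.61 ± 0.06), had the smallest adjusted p of the members. Camera called the list up (adjusted p = 3.38e-16, and 9.42e-05 with an estimated correlation). Integrins and adhesion molecules were called up (10 of 20 rose and 1 fell, 12 and 2 adjusted over the list alone, adjusted p = 1.03e-06), led by ITGAM, CD53 (0.42) and ITGB7 (0.82), while the selectin ligand SELPLG fell by 0.52. MHC class I genes (7 of 11 rose, 9 adjusted over the list alone, adjusted p = 8.69e-08) and interferon response genes (8 of 37 rose, 8 adjusted over the list alone, adjusted p = 1.15e-05) were called up. Among them were the immunoproteasome subunit PSMB9 (0.47), HLA-F (0.52), IRF1 (1.03), IFI6 (0.98) and GBP4 (1.17). Of the MYC and ribosome biogenesis genes, 14 of 33 fell and none rose (17 adjusted over the list alone, adjusted p = 4.23e-05), NOP56 by 0.24 and BOP1 by 0.33, while MYC itself was at 0.05 ± 0.04 (adjusted p = 0.442). These 5 calls held with an estimated correlation.

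A further 4 lists were called on average but not with an estimated correlation. Antigen presentation and MHC class II genes rose (5 of 13, 5 adjusted over the list alone, adjusted p = 0.00106, and adjusted p = 0.107 with an estimated correlation), led by IFI30 (0.63) and CTSS (0.47). DNA replication and mitosis genes fell (14 of 40, 14 fell and 2 rose adjusted over the list alone, adjusted p = 0.00862, and adjusted p = 0.131 with an estimated correlation), among them E2F1 (-0.31) and CCNE1 (-0.23). This list lost its call without Kasumi-1 and Sig-M5 (adjusted p = 0.217), with the mean of all probe sets (0.2) and without the dimmest genes (0.0592). Secondary and tertiary granule proteins were called up (6 of 18 rose and 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.0113, and adjusted p = 0.131 with an estimated correlation). CHI3L1 was at 1.82 and TCN1 at -0.54, and the list lost its call without Kasumi-1 and Sig-M5 (adjusted p = 0.688) and with the mean of all probe sets (0.0668). Cell cycle inhibitors were called up (4 of 10 rose and 1 fell, 4 and 2 adjusted over the list alone, adjusted p = 0.0469, and adjusted p = 0.124 with an estimated correlation). CDKN2D was at 0.47 and BTG1 at 0.28, and 21 single arrays each ended the call of the list when left out, at adjusted p-values from 0.0506 to 0.0739, as did the actin covariate (0.0689), array weights (0.0564), the replicate block (0.0709), leaving out the dimmest genes (0.0687) and leaving out Kasumi-1 and Sig-M5 (0.112).

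**Figure D2:**
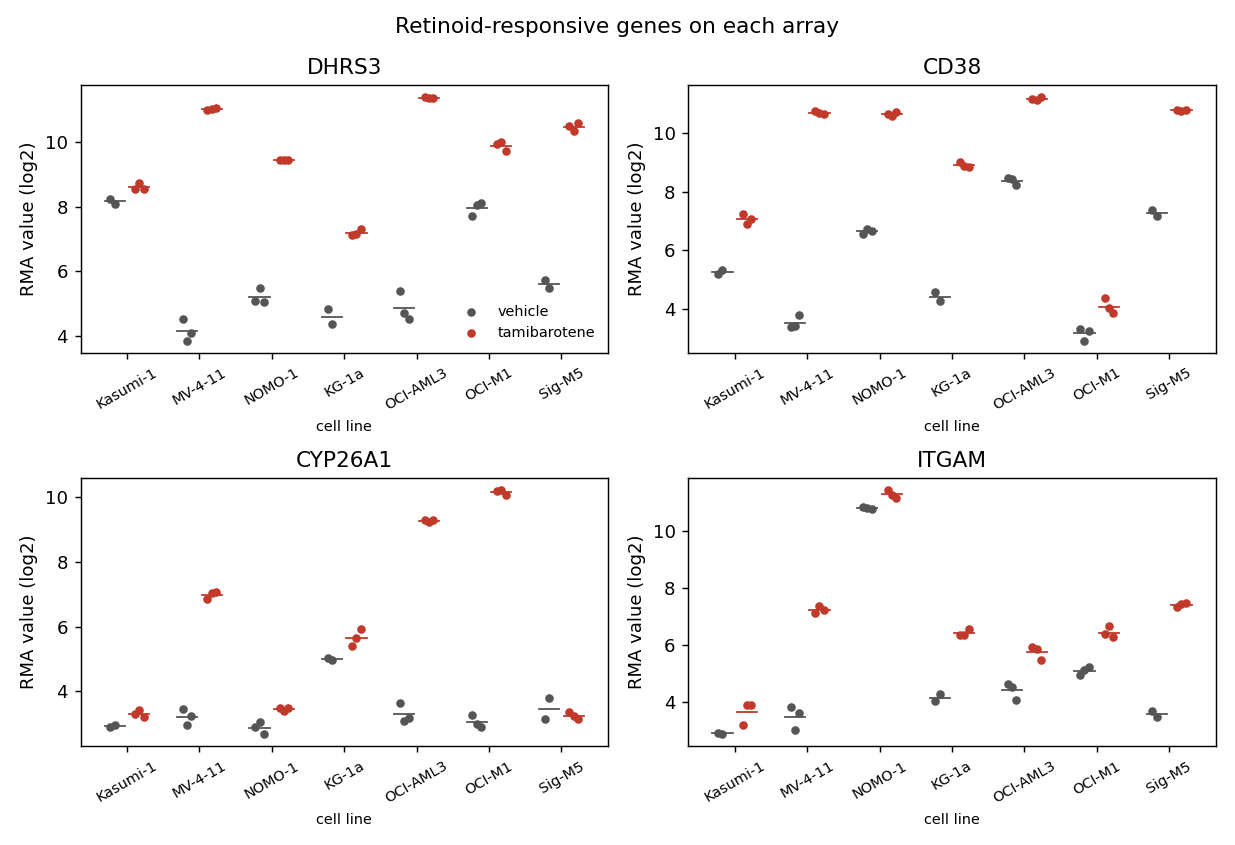
RMA values (log2) of DHRS3, CD38, CYP26A1 and ITGAM on each array, by cell line and arm, with a point for each array and a line at each group mean. CD38 is higher on every treated array of each line than on its vehicle arrays, whereas CYP26A1 ranges from a mean of 3.24 in treated Sig-M5 to 10.15 in treated OCI-M1.

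In MV-4-11, CD38 rose by 7.18 ± 0.12 from a vehicle mean of 3.52 (145-fold, adjusted p = 1.18e-27, n = 3 and 3) and DHRS3 by 6.86 ± 0.17 (116-fold), with its other probe sets at 4.80 and 1.10. The lipid-presenting molecule CD1D rose by 6.51, SLC2A5 by 5.93, the integrin ITGA6 by 5.47 and the bactericidal granule protein BPI by 4.97. The largest falls were those of the oxysterol receptor GPR183 (-3.20), the interleukin-1 antagonist IL1RN (-3.07), the calgranulin S100A8 (-3.00), TENT5C (-2.83), the transcription factor GATA2 (-2.75) and MCUB (-2.66). The SE of the 12 genes ran from 0.09 to 0.27, and they were called under every alternative applied to single genes. ITGAM rose by 3.75 and CYP26A1 by 3.78, RXRA, the partner receptor of RARA, fell by 0.93 (adjusted p = 5.62e-06), and MYC was at -0.28 (adjusted p = 0.111). ITGAM was at 2.89 and 0.82 by its other probe sets. In all, 783 genes rose and 616 fell, 236 and 107 of them at least 2-fold.

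Of the retinoic acid-induced genes in MV-4-11, 10 rose, 1 fell and 12 did not pass (11 and 3 adjusted over the list alone, adjusted p = 3.58e-15, and 0.000104 with an estimated correlation), including PLAAT4 at 3.81. Integrins and adhesion molecules rose (7 of 20 and 1 fell, 8 and 1 adjusted over the list alone, adjusted p = 1.99e-06). ICAM1 was at 1.56. Eosinophil, basophil and mast cell markers fell (4 of 12, 4 adjusted over the list alone, adjusted p = 3.95e-05), namely GATA2, FCER1A (-1.86), PRG2 (-2.04) and RNASE2 (-1.27). MYC and ribosome biogenesis genes were called down (2 of 33 fell, 5 fell and 1 rose adjusted over the list alone, adjusted p = 0.000298). NOP56 was at -0.33 and was not called when MV-4-11 was fitted alone (adjusted p = 0.097). These 4 calls held with an estimated correlation.

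The other MV-4-11 list calls did not hold with it. Antigen presentation and MHC class II genes rose (3 of 13, 5 adjusted over the list alone, adjusted p = 0.000102, and adjusted p = 0.0573 with an estimated correlation). IFI30 was at 2.27. MHC class I genes rose (4 of 11, 4 adjusted over the list alone, adjusted p = 0.000242, and adjusted p = 0.0936 with an estimated correlation). HLA-F was at 1.33. Interferon response genes rose (7 of 37, 8 rose and 1 fell adjusted over the list alone, adjusted p = 0.00891, and adjusted p = 0.0648 with an estimated correlation). GBP4 was at 2.04, IFI6 at 1.57 and IRF1 at 1.27. Primary granule proteins were called down (4 of 13 fell and 1 rose, 5 and 2 adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.162 with an estimated correlation). CTSG was at -2.14 and CST7 at -2.15, and the list lost its call with array weights (adjusted p = 0.0542). DNA replication and mitosis genes were called down as well (5 of 40, 6 adjusted over the list alone, adjusted p = 0.0249, and adjusted p = 0.21 with an estimated correlation), a call lost without tamibarotene replicate 3 (adjusted p = 0.232) or vehicle replicate 2 (adjusted p = 0.199), with array weights (0.0971), with quantile normalization (0.05) and without the dimmest genes (0.0576).

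In OCI-AML3, DHRS3 rose by 6.49 ± 0.17 from a vehicle mean of 4.88 (89.9-fold, adjusted p = 4.82e-23, n = 3 and 3), CLIC3 by 6.14, CYP26A1 by 5.97, PLAAT4 by 4.56, the G protein subunit GNG2 by 4.53 and LRG1 by 4.05. S100A8 fell by 3.11, GSAP by 2.17, LGALS3 by 2.10, the growth factor PDGFA by 2.08, the platelet chemokine PPBP by 2.07 and the potassium channel KCNN4 by 2.05. With SE from 0.11 to 0.24, these 12 were called under every alternative applied to single genes. CD38 rose by 2.81 and ITGAM by 1.34, and RXRA fell by 0.85 (adjusted p = 2.01e-05) and MYC by 0.66 (adjusted p = 1.61e-05). ITGAM was at 1.14 and 0.44 by its other probe sets. In all, 997 genes rose and 1153 fell, 264 and 90 of them at least 2-fold, and with every probe set tested 2221 probe sets rose and 2200 fell.

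Among the retinoic acid-induced genes in OCI-AML3, 12 rose, 1 fell and 10 did not pass (13 and 2 adjusted over the list alone, adjusted p = 1.32e-15, and 9.65e-05 with an estimated correlation). MYC and ribosome biogenesis genes fell in number, 22 of 33, with none risen (24 fell and 1 rose adjusted over the list alone, adjusted p = 1.4e-15), including the nucleolar proteins NOP56 (-0.61) and MRTO4 (-0.71), ornithine decarboxylase ODC1 (-0.51) and spermidine synthase SRM (-0.59). MHC class I genes rose (8 of 11, 10 adjusted over the list alone, adjusted p = 9.49e-13), HLA-F by 1.93, PSMB9 by 1.08 and HLA-C by 0.74. Interferon response genes also rose (11 of 37, 14 adjusted over the list alone, adjusted p = 3.84e-10), GBP4 by 2.51, IFI6 by 2.10 and IRF1 by 1.79. Targets of p53 were called up (4 of 23, 6 adjusted over the list alone, adjusted p = 0.00106). TP53I3 was at 3.16, TP53INP1 at 1.27 and the cyclin-dependent kinase inhibitor CDKN1A at 1.19. Integrins were called up (9 of 20 rose and 1 fell, 9 and 3 adjusted over the list alone, adjusted p = 0.00197). ITGB7 was at 2.13 and ITGAL at 1.67. Cholesterol synthesis genes were called up (4 of 16 rose and 1 fell, likewise adjusted over the list alone, adjusted p = 0.00397). DHCR7 was at 0.74 and SQLE at 0.69. These 7 calls held with an estimated correlation.

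Of the OCI-AML3 list calls lost with it, amino acid and ER stress genes fell (9 of 24 fell and 1 rose, 10 and 3 adjusted over the list alone, adjusted p = 0.00161, and adjusted p = 0.0724 with an estimated correlation), among them TRIB3 (-0.94), asparagine synthetase ASNS (-0.72) and the stress regulator ATF4 (-0.47). Cell cycle inhibitors rose (3 of 10 and 1 fell, likewise adjusted over the list alone, adjusted p = 0.0113, and adjusted p = 0.0565 with an estimated correlation). CDKN2D was at 0.76 and BTG1 at 0.58. Genes of lipid handling rose (5 of 19 and 2 fell, 8 and 3 adjusted over the list alone, adjusted p = 0.018, and adjusted p = 0.115 with an estimated correlation). CD36 was at 1.68 and APOC1 at 1.05, and the list lost its call with the mean of all probe sets (adjusted p = 0.212) and without the dimmest genes (adjusted p = 0.065). Cell death regulators were called up (6 of 23 rose and 1 fell, 6 and 2 adjusted over the list alone, adjusted p = 0.0414, and adjusted p = 0.0656 with an estimated correlation). The pro-apoptotic BIK was at 2.77 and the anti-apoptotic BCL2 at -1.87. The list of cell death regulators lost its call without tamibarotene replicate 1 (adjusted p = 0.143), vehicle replicate 2 (0.0632) or vehicle replicate 3 (0.0598), with array weights (0.165), the mean of all probe sets (0.149) or the replicate block (0.104), and without the dimmest genes (0.107). DNA replication and mitosis genes were called down (3 of 40, likewise adjusted over the list alone, adjusted p = 0.0498, and adjusted p = 0.286 with an estimated correlation). CDC45 was at -0.39. The list lost its call without tamibarotene replicate 1 (0.0529) or 2 (0.105) or vehicle replicate 1 (0.109) or 3 (0.177), with quantile normalization (0.126) or the replicate block (0.0566), and without the dimmest genes (0.116).

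Sig-M5 had the highest number of called genes with all arrays, and its vehicle arrays had actin differences of 0.81 and 1.89. CLIC3 rose by 5.25 ± 0.14 from a vehicle mean of 3.82 (38.2-fold, adjusted p = 3.95e-22, n = 3 and 2), CD1D by 5.15, GNG2 by 5.01, the myeloid tyrosine kinase FGR 32-fold, DHRS3 by 4.86 and the granule protein CHI3L1 by 4.55. The intermediate filament VIM fell by 3.68, GATA2 by 3.63, the cytokine TNF by 3.37, BAHCC1 by 2.56, IL1RN by 2.52 and BCL11A by 2.46. These 12 genes, with SE from 0.13 to 0.27, were called under every alternative applied to single genes. CD38 rose by 3.51 and ITGAM by 3.83, and RXRA fell by 2.35 (adjusted p = 3.08e-13) by the probe set used, whereas its other probe set was at -1.10. ITGAM was at 2.58 and 1.39 by its other probe sets, and DHRS3 at 3.72 and 0.14 by its own. CYP26A1 was at -0.23 ± 0.17 (adjusted p = 0.352). RARA fell by 0.67 (adjusted p = 0.00592) and MYC rose by 0.59 (adjusted p = 0.000203), but without vehicle replicate 2 RARA was at -0.41 (adjusted p = 0.241) and MYC at 0.28 (adjusted p = 0.0905).

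In Sig-M5, 1541 genes rose and 3333 fell, 406 and 243 of them at least 2-fold. With every probe set tested, 6212 probe sets rose and 6882 fell, so the excess of falls was far smaller there. With the actin difference as a covariate 1705 genes were called, against 2374 in OCI-AML3, with array weights 3255, against 5639 in OCI-AML3, and without vehicle replicate 2 the count was 2700, with 804 rises and 1896 falls. The median of all genes was shifted by -0.096 as deposited, by -0.113 after quantile normalization and by -0.146 after centring each array on its median. It was shifted by -0.13 without the dimmest genes, but only by -0.073 with the actin covariate and by -0.06 with the mean of all probe sets.

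Of 40 DNA replication and mitosis genes in Sig-M5, 20 fell and none rose (20 adjusted over the list alone, adjusted p = 1.22e-05), including the helicase subunit MCM7 (-0.76), the replication licensing factors CDC6 (-1.06) and CDT1 (-1.02), and E2F1 (-1.28). Of the retinoic acid-induced genes, 10 rose, 4 fell and 9 did not pass (11 and 4 adjusted over the list alone, adjusted p = 3.8e-05). DHRS9 was at 1.19. Granulocyte maturation markers were called up (8 of 21 rose and 4 fell, 9 and 4 adjusted over the list alone, adjusted p = 0.00026). S100A8 was at 1.21 and S100A9 at 1.14. Integrins and adhesion molecules were called up (8 of 20 rose and 2 fell, likewise adjusted over the list alone, adjusted p = 0.000494). CD53 was at 1.40 and CD44 at 1.04. Cell cycle inhibitors rose (3 of 10, likewise adjusted over the list alone, adjusted p = 0.00627). BTG1 was at 1.09. Cell death regulators were called up (5 of 23 rose and 4 fell, 7 and 5 adjusted over the list alone, adjusted p = 0.0156). BCL2A1 was at 3.46 and BCL2L11 at 1.60, and the list lost its call without vehicle replicate 2 (adjusted p = 0.0504) or the dimmest genes (0.128), and with the actin covariate (0.0888) or the replicate block (0.0709). These 6 calls held with an estimated correlation. Secondary and tertiary granule proteins were called up (6 of 18 rose and 3 fell, likewise adjusted over the list alone, adjusted p = 0.0009, and adjusted p = 0.0544 with an estimated correlation). ORM1 was at 2.90, ARG1 at 2.10 and lactoferrin LTF at 1.49.

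**Figure D3:**
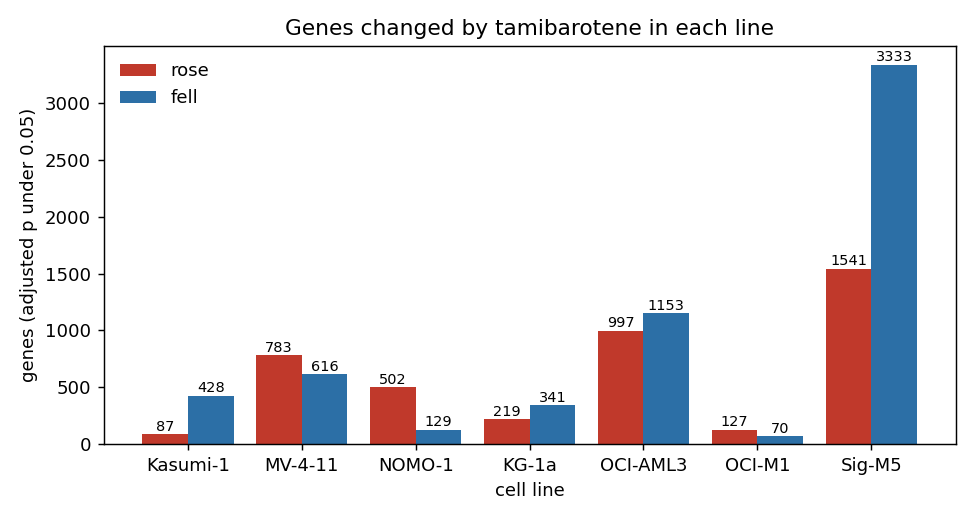
Number of genes that rose or fell with tamibarotene at a limma adjusted p under 0.05 in each cell line, as bars. The counts run from 127 rises and 70 falls in OCI-M1 to 1541 rises and 3333 falls in Sig-M5, whose vehicle arrays had actin differences of 0.81 and 1.89.

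In NOMO-1, DHRS3 rose by 4.25 ± 0.17 to a treated mean of 9.45 (adjusted p = 1.32e-17, n = 3 and 3), CD38 by 4.02, GNG2 by 3.55, CD1D by 3.18, the leukocyte receptor LILRA5 by 3.10 and the sterol hydroxylase CYP27A1 by 3.00. The prostaglandin dehydrogenase HPGD fell by 2.19, MS4A3 by 1.76, the proteoglycan VCAN by 1.62, HHLA2 by 1.35, the connexin GJB2 by 1.27 and the desmosomal cadherin DSG2 by 1.25, with SE of the 12 genes from 0.12 to 0.32. CYP26A1 rose by 0.58 (adjusted p = 0.022), and ITGAM, already at 10.82 in vehicle, was at 0.47 (adjusted p = 0.172). In all, 502 genes rose and 129 fell, 90 and 19 of them at least 2-fold. The count was 404 without tamibarotene replicate 2 (331 rises and 73 falls), 984 without vehicle replicate 2 (666 and 318), 399 without vehicle replicate 3 (306 and 93) and 1002 with the replicate block (607 and 395), and 202 when the line was fitted alone, where VCAN, HHLA2 and DSG2 were not called (adjusted p = 0.107, 0.0774 and 0.284). By correlation across genes, NOMO-1 vehicle replicate 2 was closest to tamibarotene replicate 2 (r = 0.9944). DSG2 was also not called without tamibarotene replicate 1 (adjusted p = 0.0676), vehicle replicate 1 (0.0506) or vehicle replicate 3 (0.107), nor CYP26A1 without tamibarotene replicate 1 (0.0922) or 3 (0.0774) or vehicle replicate 1 (0.0616) or 3 (0.172).

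The retinoic acid-induced genes were called up in NOMO-1 (6 rose, 1 fell and 16 did not pass, 8 and 1 adjusted over the list alone, adjusted p = 1.19e-09). PLAAT4 was at 2.39 and ASB2, a ubiquitin ligase subunit, at 1.93. Interferon response genes rose (10 of 37, 11 adjusted over the list alone, adjusted p = 1.44e-07). GBP4 was at 2.16, IRF1 at 1.77 and PSMB9 at 0.68. Antigen presentation and MHC class II genes rose too (4 of 13, 7 adjusted over the list alone, adjusted p = 6.87e-06). IFI30 was at 0.83. Integrins rose (4 of 20, 6 adjusted over the list alone, adjusted p = 0.0023). ITGAL was at 0.95 and CD53 at 0.76, and the list lost its call without vehicle replicate 2 (adjusted p = 0.0538). MYC and ribosome biogenesis genes were called down (1 of 33, likewise adjusted over the list alone, adjusted p = 4.43e-05), with a mean of -0.17. No DNA replication or mitosis gene passed the test, over all genes or over the list alone, but camera called the 40 genes down (adjusted p = 0.000134), with a mean of -0.23. These 6 calls held with an estimated correlation. MHC class I genes rose (4 of 11, likewise adjusted over the list alone, adjusted p = 4.28e-05, and adjusted p = 0.0627 with an estimated correlation). Retinoid metabolism and receptor genes were called up (2 of 19 rose, DHRS3 and CYP26A1, likewise adjusted over the list alone, adjusted p = 0.00302, and adjusted p = 0.107 with an estimated correlation). Genes of lipid handling were called up (4 of 19 rose and 1 fell, likewise adjusted over the list alone, adjusted p = 0.017, and adjusted p = 0.112 with an estimated correlation). CD36 was at 1.63, and the list lost its call without vehicle replicate 2 (adjusted p = 0.0582) or with the mean of all probe sets (adjusted p = 0.179). Primary granule proteins were called down (1 of 13 fell, MS4A3, and 2 adjusted over the list alone, adjusted p = 0.0199, and adjusted p = 0.188 with an estimated correlation), and the call was lost without tamibarotene replicate 3 (0.0654) or vehicle replicate 1 (0.0901) or 2 (0.0829) and with the replicate block (0.0546).

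In KG-1a, CD38 rose by 4.50 ± 0.14 from a vehicle mean of 4.41 (22.7-fold, adjusted p = 2.24e-20, n = 3 and 2), the secreted protein ISM1 by 3.15, the homeobox factor HLX by 2.82, SLC2A5 by 2.71, DHRS3 by 2.60 and LRRC32, which anchors latent transforming growth factor beta, by 2.48. The transcription factor SNAI2 fell by 2.37, the BMP antagonist NOG by 2.34, MAGEF1 by 2.12, the hedgehog-binding HHIP by 2.04, SMIM14 by 2.01 and the tetraspanin CD53 by 1.66. The SE of these genes was 0.10 to 0.21, and their calls held under every alternative applied to single genes. CD53 was called up in 5 other lines (difference of KG-1a from the other lines -2.43, adjusted p = 2.2e-15). ITGAM rose by 2.25, with its other probe sets at 1.62 and 0.52. By its other probe sets DHRS3 was at 1.40 and 0.11. CYP26A1 rose by 0.66 (adjusted p = 0.0192), and the call was lost without tamibarotene replicate 2 (0.052) or 3 (0.129) or vehicle replicate 1 (0.122) or 2 (0.247), when the line was fitted alone (0.0641) and with the replicate block (0.138). In all, 219 genes rose and 341 fell, 71 and 46 of them at least 2-fold. The count was 283 without vehicle replicate 1 (139 rises and 144 falls), 260 without vehicle replicate 2 (117 and 143) and 728 with the replicate block (357 and 371).

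Of the retinoic acid-induced genes in KG-1a, 8 rose, none fell and 15 did not pass (8 adjusted over the list alone, adjusted p = 4.03e-08, and 0.0029 with an estimated correlation). PLAAT4 was at 1.24. DNA replication and mitosis genes were called up (1 of 40 rose, 3 adjusted over the list alone, adjusted p = 0.000954, and adjusted p = 0.0642 with an estimated correlation). The ribonucleotide reductase subunit RRM2 was at 0.54. Granulocyte maturation markers were called up (4 of 21 rose and 1 fell, 4 and 2 adjusted over the list alone, adjusted p = 0.0324, and adjusted p = 0.21 with an estimated correlation). S100A9 was at 1.23 and S100P at 0.95, although the median member was at -0.01 and the list lost its call without tamibarotene replicate 1 (adjusted p = 0.0555), with array weights (0.0858) and with the replicate block (0.051). Primary granule proteins were called down (4 of 13 fell and 1 rose, 5 and 1 adjusted over the list alone, adjusted p = 0.0443, and adjusted p = 0.268 with an estimated correlation). CTSG was at -1.06 and the proteoglycan SRGN at 1.02, and the list lost its call without tamibarotene replicate 1 (0.11), vehicle replicate 1 (0.368) or the dimmest genes (0.105), and with the actin covariate (0.076), array weights (0.147) or the replicate block (0.0507). Lysozyme LYZ fell by 1.58 with all arrays and was at -0.19 without vehicle replicate 1 (adjusted p = 0.754).

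In OCI-M1, the line with the fewest called genes when all arrays were used, CYP26A1 rose by 7.10 ± 0.15 from a vehicle mean of 3.05 (137-fold, adjusted p = 3.54e-25, n = 3 and 3). The heme synthesis enzyme ALAS1 rose by 1.93, DHRS3 by 1.92, LRATD1 by 1.73, PRAM1 by 1.63 and the chemokine CCL2 by 1.62. Albumin, ALB, fell by 2.40, the WNT ligand WNT5B by 1.42, SAMSN1 by 1.35, the IgE receptor subunit FCER1A by 1.26, CD69 by 1.24 and MEX3B by 1.20, with SE of the 12 genes from 0.12 to 0.27. CD38 rose by 0.92 and ITGAM by 1.34, with the other ITGAM probe sets at 1.02 and 0.05. SAMSN1 was not called without vehicle replicate 1 (adjusted p = 0.0598), and CD38 (0.0611) and CD69 (0.0586) were not called when the line was fitted alone, where 63 genes were called. In all, 127 genes rose and 70 fell, 30 and 9 of them at least 2-fold. Fewer genes were called in Kasumi-1 than in OCI-M1 with the actin covariate (28 against 250), with array weights (14 against 414), with each line fitted alone (0 against 63), at an adjusted p under 0.01 (66 against 114) and with a log2 fold change of at least 1 (24 against 39). By correlation across genes, OCI-M1 vehicle replicate 1 was closest to tamibarotene replicate 1.

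Of the retinoic acid-induced genes in OCI-M1, 7 rose, none fell and 16 did not pass (7 adjusted over the list alone, adjusted p = 6.25e-13, and 0.00024 with an estimated correlation). PLAAT4 was at 1.24. The other 4 list calls were lost with an estimated correlation. Retinoid metabolism and receptor genes were called up (2 of 19 rose, CYP26A1 and DHRS3, likewise adjusted over the list alone, adjusted p = 0.0383, and adjusted p = 0.274 with an estimated correlation), and the call was lost without tamibarotene replicate 1 (0.068) or vehicle replicate 1 (0.0793) or 3 (0.0528), with array weights (0.149) or the replicate block (0.18), and without the dimmest genes (0.513). The median of these 19 genes was 0.00. Secondary and tertiary granule proteins were called down (1 of 18 fell, TCN1, a vitamin B12 carrier, at -1.16, likewise adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.168 with an estimated correlation), and the call was lost without tamibarotene replicate 3 (0.05) or vehicle replicate 1 (0.127) or 2 (0.0931), with array weights (0.0542) and with the mean of all probe sets (0.204). Without the dimmest genes the direction of that test turned (adjusted p = 0.968). Eosinophil, basophil and mast cell markers were called down (1 of 12 fell, FCER1A, likewise adjusted over the list alone, adjusted p = 0.0414, and adjusted p = 0.203 with an estimated correlation), and the call was lost without tamibarotene replicate 1 (0.0745) or 2 (0.0681) or vehicle replicate 1 (0.12) or 3 (0.0683), with array weights (0.103) or the replicate block (0.0758), and without the dimmest genes (0.0991). Cell cycle inhibitors were called up with no member past the test over all genes (4 of 10 adjusted over the list alone, adjusted p = 0.0386, and adjusted p = 0.108 with an estimated correlation), and the call was lost without tamibarotene replicate 2 (0.0995) or 3 (0.127) or vehicle replicate 1 (0.104) or 2 (0.0851). Cell cycle inhibitors in OCI-M1 were also not called with the actin covariate (0.076), array weights (0.0569), quantile normalization (0.05), the mean of all probe sets (0.0565) or the replicate block (0.0659), nor without the dimmest genes (0.151).

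In Kasumi-1, whose vehicle replicate 2 had an actin difference of 1.18, CD38 rose by 1.80 ± 0.14 from a vehicle mean of 5.26 (3.49-fold, adjusted p = 1.72e-09, n = 3 and 2). The succinate receptor SUCNR1 rose by 1.37, ANKRD12 by 1.19, thyrotropin-releasing hormone TRH by 0.91, FAM117A by 0.90 and DENND6B by 0.81. TENT5C fell by 1.72, the interleukin-6 receptor IL6R by 1.45, the adrenergic receptor ADRA2A by 1.23, MYO18B by 1.20, GPRASP1 by 1.19 and LOC105372733 by 1.16, with SE of the 12 genes from 0.12 to 0.30. DHRS3 was at 0.44 (adjusted p = 0.199) and CYP26A1 at 0.38 (adjusted p = 0.215), and ITGAM rose by 0.77 (adjusted p = 0.0309), with its other probe sets at 0.24 and 0.13. In all, 87 genes rose and 428 fell, 3 and 21 of them at least 2-fold. After centring each array on its median, 47 rose and 885 fell.

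The Kasumi-1 count was 1115 without tamibarotene replicate 1 (366 rises and 749 falls), 36 without tamibarotene replicate 2 (12 and 24), 15 without vehicle replicate 2 (6 and 9), 1834 without vehicle replicate 3 (404 and 1430), 1934 with the replicate block (721 and 1213) and 28 with the actin covariate (8 and 20). Without both tamibarotene replicate 1 and vehicle replicate 2 it was 184, with 111 rises and 73 falls, so the balance of rises and falls among the called genes changed. With the line fitted alone in limma it was 0, with 1728 genes at an unadjusted p under 0.05. Among the alternatives applied to single genes, CD38, TENT5C, GPRASP1 and FAM117A lost their calls in that fit alone (adjusted p = 0.204, 0.397, 0.397 and 0.397), whereas IL6R was also lost with the mean of its probe sets (adjusted p = 0.0666). The other 7 largest changes, and ITGAM, were lost without at least vehicle replicate 2, at adjusted p-values from 0.133 for ANKRD12 to 0.544 for MYO18B, and without tamibarotene replicate 2 except ADRA2A, at 0.0505 for LOC105372733 to 0.197 for ITGAM. ANKRD12 (0.0541) and ITGAM (0.0923) were not called without tamibarotene replicate 3 either, nor ANKRD12 (0.0589), DENND6B (0.0792) and ITGAM (0.0596) without vehicle replicate 3.

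Of the retinoic acid-induced genes in Kasumi-1, CD38, ITGAM and PLAAT4 (0.80) rose, none fell and 20 did not pass (3 adjusted over the list alone). Camera called the list up (adjusted p = 0.0113, and adjusted p = 0.143 with an estimated correlation), and the call was lost without vehicle replicate 3 (adjusted p = 0.265) or with the replicate block (adjusted p = 0.0627). MHC class I genes were called up (2 of 11 rose, 4 rose and 1 fell adjusted over the list alone, adjusted p = 0.0314, and adjusted p = 0.36 with an estimated correlation). PSMB9 was at 0.67, and the list lost its call without tamibarotene replicate 3 (0.234) or vehicle replicate 3 (0.197), and with the actin covariate (0.0563), the mean of all probe sets (0.0762) or the replicate block (0.0676). Cholesterol synthesis genes were called down (1 of 16 fell, MSMO1 at -0.49, likewise adjusted over the list alone, adjusted p = 0.0469, and adjusted p = 0.0963 with an estimated correlation). The call was lost without tamibarotene replicate 1 (0.0533) or 3 (0.0815), without vehicle replicate 2, alone or together with tamibarotene replicate 1, and without the dimmest genes (0.211). The cholesterol synthesis list was also not called with the actin covariate (0.134), quantile normalization (0.179) or the mean of all probe sets (0.317). PLAAT4 (0.264) and PSMB9 (0.0732) were not called without vehicle replicate 2 either, nor was MSMO1 (0.353), which also lost its call without tamibarotene replicate 2 (0.172) or 3 (0.0724).

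**Figure D4:**
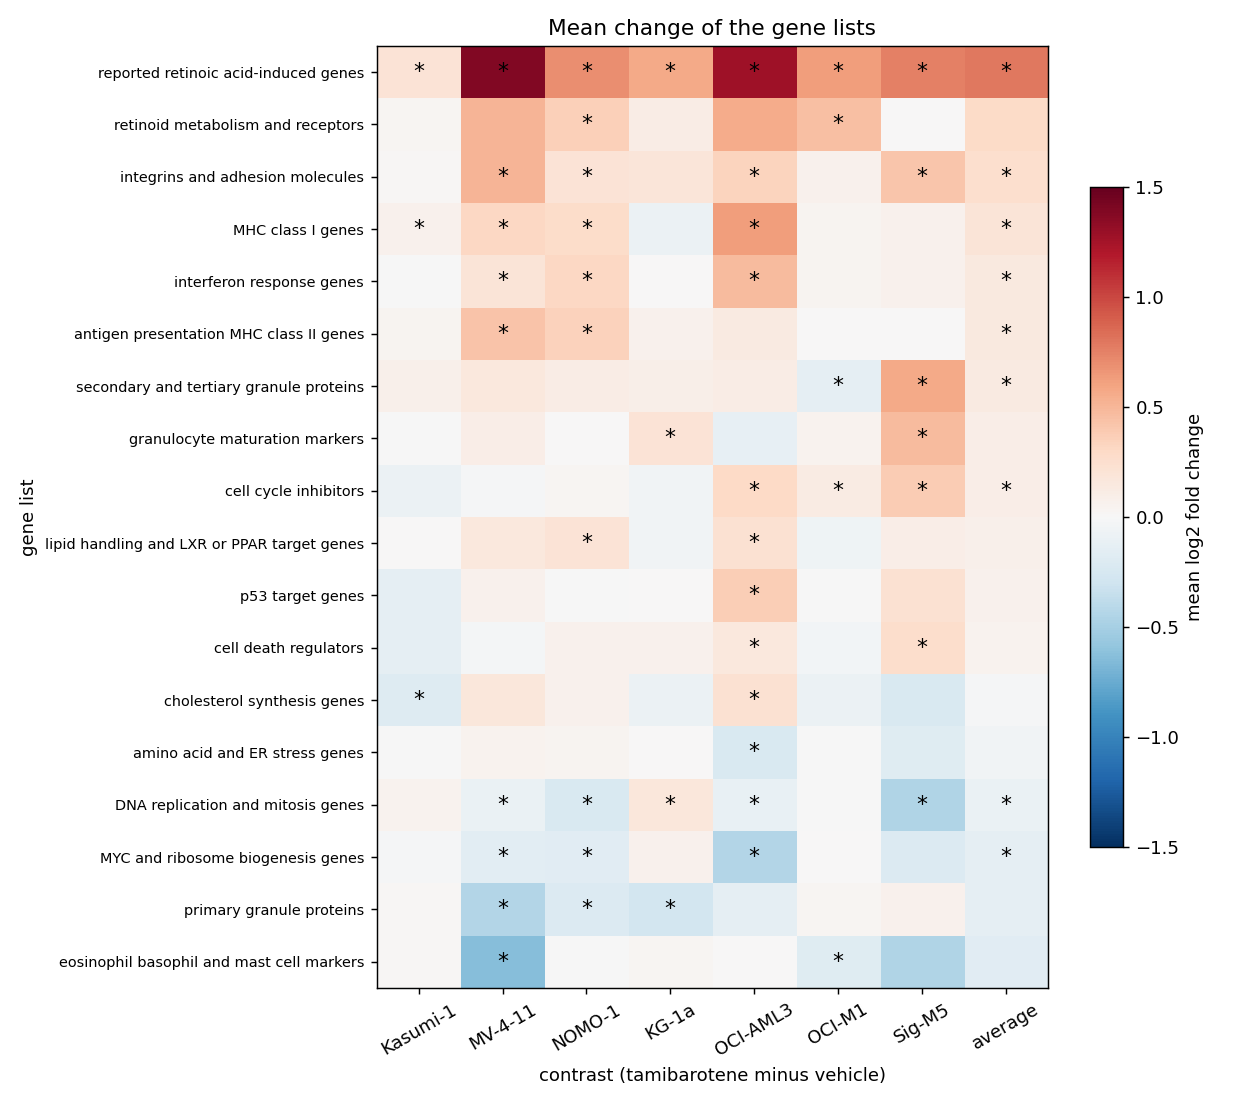
Mean log2 fold change of the members of each list called in at least 1 contrast, by line and for the average of the 7 lines, as colours from -1.5 to 1.5, with an asterisk at a camera adjusted p under 0.05. The retinoic acid-induced genes are called up in each of the 7 lines, and the DNA replication genes are called down in MV-4-11, NOMO-1, OCI-AML3 and Sig-M5 and up in KG-1a. With an estimated correlation the first list is not called in Kasumi-1 (adjusted p = 0.143), nor the DNA replication genes in MV-4-11 (0.21), OCI-AML3 (0.286) and KG-1a (0.0642).

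The comparison between lines asks whether the response depends on the line, and 4974 genes differed by limma's moderated F test. CYP26A1 had the smallest p (F = 376, adjusted p = 1.52e-22): its change ran from 7.10 in OCI-M1, 5.97 in OCI-AML3 and 3.78 in MV-4-11 to 0.38 in Kasumi-1 and -0.23 in Sig-M5. CD1D rose in MV-4-11, Sig-M5, OCI-AML3 (3.54) and NOMO-1, and stood at -0.53 in Kasumi-1, -0.25 in KG-1a and 0.24 in OCI-M1. CLIC3 rose by 4.45 in MV-4-11 and 2.48 in KG-1a besides OCI-AML3 and Sig-M5, and stood at 0.06 in Kasumi-1 and 0.15 in OCI-M1. The apolipoprotein APOC1 rose by 3.99 in MV-4-11, against -0.02 in Sig-M5. SEL1L3 rose by 4.93 in MV-4-11 and fell by 1.02 in Kasumi-1 and 1.15 in KG-1a. The prostaglandin synthase PTGS1 rose by 3.87 in OCI-AML3 and stood at 0.03 in OCI-M1. S100A8 fell in MV-4-11 and OCI-AML3 and rose in Sig-M5, where its change differed from that of the other lines by 2.31 (adjusted p = 1.58e-13). RXRA also differed (F = 30.4), with its fall in Sig-M5 exceeding that of the other lines by a difference of -1.94 (adjusted p = 2.76e-10) by the probe set used. The other RXRA probe set was at -1.10 in both Sig-M5 and OCI-AML3 and at -0.85 in MV-4-11, so the size of this difference depended on the probe set.

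Of the genes called on average, 2432 of 3460 also differed between lines. 6978 genes were called in at least 1 line, and 556 of these rose in some line and fell in another. The count of differing genes was 2946 without Sig-M5 and 2728 without Kasumi-1 and Sig-M5.

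Calls overlapped between lines in 37 of 42 tests, in 21 of 21 for rises and 16 of 21 for falls, by a one-sided Fisher's exact test after adjustment. All lines share the same pooled spread for a gene, so a gene with a low spread is more easily called in every line. The number expected of independent lists can therefore be too low, by an amount that was not tested. This matters most for overlaps close to it, such as the 33 falls shared by NOMO-1 and Sig-M5 (23.7 expected). MV-4-11 and OCI-AML3 shared 433 rises, against 43.1 expected of independent lists, and 272 falls, against 39.2, and their fold changes correlated at r = 0.56 across genes, which are not independent replicates. NOMO-1 shared 247 rises with MV-4-11 (21.7 expected) and 279 with OCI-AML3 (27.6 expected). OCI-AML3 and Sig-M5 shared 361 rises (84.7 expected) and 543 falls (212 expected). The overlaps of falls that did not pass were those of Kasumi-1 with NOMO-1 (6 against 3.05), KG-1a (7 against 8.05) and OCI-M1 (3 against 1.65), and those of OCI-M1 with NOMO-1 (2 against 0.498) and Sig-M5 (18 against 12.9). The lowest correlation of fold changes was -0.09, between NOMO-1 and KG-1a.

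RARA, the receptor that the drug binds, differed between the vehicle arrays of the lines (F = 27, adjusted p = 3.34e-10). Its mean level was 9.11 ± 0.36 (SD, n = 2) in Sig-M5, 8.49 ± 0.33 (n = 3) in OCI-AML3 and 8.38 ± 0.04 (n = 3) in MV-4-11. The other lines had 7.80 ± 0.14 (n = 3) in OCI-M1, 7.61 ± 0.04 (n = 2) in KG-1a, 7.58 ± 0.01 (n = 2) in Kasumi-1 and 7.17 ± 0.34 (n = 3) in NOMO-1. The Sig-M5 level comes from the vehicle arrays with actin differences of 0.81 and 1.89, and the order of the lines depended on the probe set. Sig-M5 was at 8.04 by another RARA probe set, below MV-4-11 (8.55) and OCI-AML3 (8.35), and at 6.38 by a further one, below MV-4-11 (7.26) and OCI-AML3 (7.07). RXRA ranged from 6.47 in OCI-M1 to 10.07 in MV-4-11 (F = 160), whereas by its other probe set OCI-AML3 was highest at 8.35, with MV-4-11 at 7.60, and OCI-M1 and Kasumi-1 were lowest at 5.74. Differences between vehicle arrays were smaller for RXRB (F = 17.9), RARG (F = 6.51) and RARB (F = 4.49). The response of RARA to the drug did not pass the test between lines (adjusted p = 0.0549), nor did those of RARB (0.721), RARG (0.218) and RXRB (0.329). RARB was at -0.26 in OCI-AML3 by the probe set used, whereas its other two probe sets were at 1.64 and 1.43 there.

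The series chose a RARA agonist, so the RARA level was set against the response over the 7 lines. The number of called genes rose with the RARA level (Pearson r = 0.88, exact permutation p = 0.00734, adjusted p = 0.0294 over 4 relations, Spearman rho = 0.68, exact permutation p = 0.11, adjusted p = 0.222). Without Sig-M5 and OCI-AML3, the lines farthest from the median RARA level, r was 0.64. Without Sig-M5 alone it was 0.80 (exact permutation adjusted p = 0.153) and fell to -0.76 once OCI-AML3 and MV-4-11 were left out too, so the relation rests on the 3 lines with the highest RARA level. With the actin covariate, which called 1705 genes in Sig-M5 and 2374 in OCI-AML3, r was 0.76 (exact permutation p = 0.0476, adjusted p = 0.19). The adjusted p was 0.291 with array weights, 0.0603 with the mean of the RARA probe sets and 0.0968 with the replicate block, and it rose above 0.05 without Kasumi-1 vehicle replicate 3 (0.0754) or NOMO-1 vehicle replicate 2 (0.0571). It did so as well without Kasumi-1 (0.0611), MV-4-11 (0.128), KG-1a (0.0556) or OCI-AML3 (0.128). The other 3 relations did not pass the exact permutation test. They were those of the mean change of the 22 retinoic acid-induced genes other than RARB (r = 0.52, exact p = 0.227, adjusted p = 0.302, rho = 0.64, p = 0.139, adjusted p = 0.222), DHRS3 (r = 0.58, exact p = 0.168, adjusted p = 0.302, rho = 0.61, p = 0.167, adjusted p = 0.222) and CD38 (r = 0.18, exact p = 0.703, adjusted p = 0.703, rho = 0, p = 1, adjusted p = 1). Their r without Sig-M5 and OCI-AML3 was 0.71, 0.51 and 0.48.

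**Figure D5:**
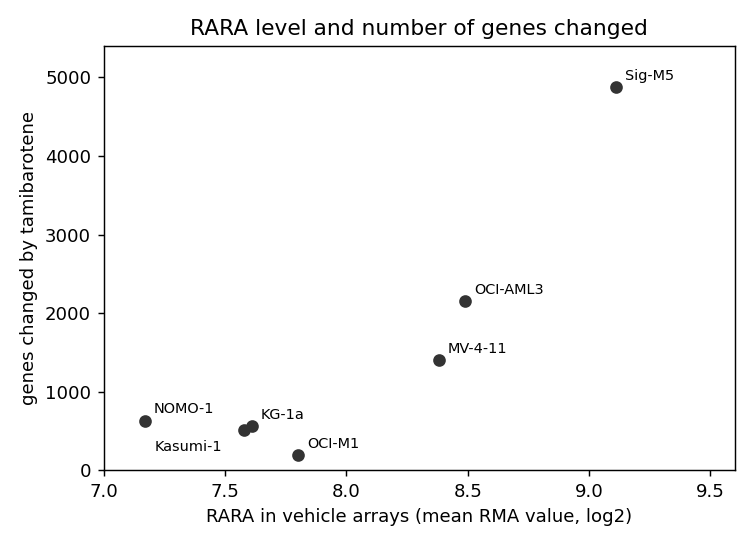
Number of genes called in each line against the mean RARA value (log2) of its vehicle arrays, with a point for each of the 7 lines. Sig-M5, at 9.11, has 4874 called genes, and the 4 lines with a RARA value of 7.80 or less have 197 to 631.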

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

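The tests of the actin covariate on the Sig-M5 count, on its rises of at least 2-fold and on CYP26A1, and the tests of a mislabelled array, of RNA integrity in Kasumi-1 and of a weak retinoid response in Sig-M5 were chosen only after the result was seen. The correlation of the Sig-M5 changes with the difference between the Kasumi-1 vehicle arrays was chosen after the actin values were seen, but before its own result.

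The response to tamibarotene differed between lines for 4974 genes by limma's moderated F test over the 7 lines. The F value was 376 for CYP26A1, 370 for CD1D, 368 for CLIC3, 323 for APOC1, 297 for SEL1L3, 261 for CD38, 251 for SLC2A5, 229 for FGR, 196 for S100A8 and 193 for PTGS1. Among the genes named in every comparison, it was also past the threshold for DHRS3 (184), ITGAM (55.1), RXRA (30.4) and MYC (14.5). What drew attention to these genes is the tested difference between lines. Of 4305 probe sets with no or several gene symbols, which enter no comparison between genes, 319 rose on average over the lines, measured against the vehicle arrays, and 371 fell.

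Sig-M5 had the highest number of called genes, 4874, with more falls than rises, an excess that was far smaller over every probe set (6212 rises and 6882 falls), and its vehicle arrays had actin differences of 0.81 and 1.89. With the actin difference as a covariate, the median of the rises of at least 2-fold moved from 1.37 to 1.19 and 285 of 406 were still called. Of the falls of at least 2-fold, 174 of 243 were still called, with the median moving from -1.18 to -0.94. The covariate itself passed the threshold for 1263 genes. Its linear slope for a gene is the same in all lines, and both Sig-M5 vehicle arrays lay above every treated one. It therefore cannot separate lower integrity from the drug as the cause of these changes. For the number of called genes, lower integrity and the response of the line cannot be told apart. The covariate left 1705 calls, against 2374 in OCI-AML3. In the genes called without it, the median size of the change went from 0.58 to 0.43. Their median SE went from 0.14 to 0.19, so calls ended through both. With array weights, which do not use the actin difference, Sig-M5 was not the highest either, at 3255 against 5639 in OCI-AML3. That rank cannot decide the question, because the estimation of the weights did not converge. OCI-AML3 vehicle replicate 1 got a weight of 10.13, and OCI-AML3 had 2150 calls without weights. The Sig-M5 changes correlated at r = 0.33 across genes with the difference between the better and the poorer Kasumi-1 vehicle array, against at most 0.11 for the other lines, in line with integrity having a part in the changes, although genes are not independent replicates. The difference of the line itself stays open and untested.

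Kasumi-1 had 428 falls among 515 called genes, and its arrays did not group by arm, with tamibarotene replicate 1 and vehicle replicate 3 closest to each other, whereas in NOMO-1 and OCI-M1 a single vehicle array each was closest to a treated one. Argued against is a mislabelled tamibarotene replicate 1: over 20 genes that rose in at least 5 of the other 6 lines and did so in replicates 2 and 3, it lay at a median position of 0.99, where vehicle is 0 and the other treated replicates are 1. Lower integrity of vehicle replicate 2 may have a part in the calls, since 15 genes were called without that array and 1834 without vehicle replicate 3, each count resting on a single vehicle array, but the drop is not particular to that array, as 36 were called without tamibarotene replicate 2, whose actin difference was 0.21. Without tamibarotene replicate 1 and vehicle replicate 2 together 111 genes rose and 73 fell, so the excess of falls was not there without these arrays. A difference between cultures stays open and untested.

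CYP26A1 rose by 7.10 in OCI-M1, where 197 genes were called, and was at -0.23 ± 0.17 in Sig-M5. A weak retinoid response of Sig-M5 as a whole is argued against by the 21 retinoic acid-induced genes other than CYP26A1 and RARB, whose mean change was 0.84 ± 0.05 in Sig-M5 and 0.36 ± 0.04 in OCI-M1. Low integrity of the Sig-M5 vehicle arrays hiding a rise is argued against by the treated Sig-M5 arrays, at 3.37, 3.23 and 3.14, against a vehicle mean of 3.05 in OCI-M1. With the actin covariate, whose slope is shared by all lines, the change in Sig-M5 was 0 ± 0.24. A difference between the lines in the control of CYP26A1, which the design names through the lines, remains a hypothesis found and not tested further on these data.

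Chance as the source of the counts was examined with other splits of the same arrays. For the average over lines, 3460 genes were called and at most 121 in 99 random splits within the lines. Thus 1 of 100 splits, the real one, gave as many, which argues against chance and is the smallest share these splits can give. For the differences between lines the counts were 4974 and at most 1054. The random splits remove the drug effect itself, so they cannot test whether that effect differs between lines. The 10 splits of a single line are too few for a share under 0.05. The real count and the highest other were 1399 and 22 in MV-4-11, 631 and 9 in NOMO-1, 560 and 16 in KG-1a, 2150 and 1 in OCI-AML3 and 4874 and 1986 in Sig-M5, and in each of these lines 1 split, the real one, gave as many. In OCI-M1, 197 genes were called, against at most 15 in the other splits and at most 1 in the splits that part all 3 pairs of same-numbered arrays as the real one does. The others part 1 pair. In Kasumi-1, 2 of the 10 splits gave as many genes as the real 515, and the split that set tamibarotene replicates 2 and 3 apart from the other arrays gave 927, which points to a structure of the samples besides the arm.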

How the results depend on the processing

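The tests with the actin covariate, without 2 Kasumi-1 arrays together and without Kasumi-1 and Sig-M5 together were chosen only after the result was seen.

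For single genes and lists, 18737 of 19950 alternative values kept their side of the threshold, 1084 were no longer past it and 117 came to be past it. A further 12 changed sign where the main or the alternative value was called. Changes of sign where neither was called are among the 18737 and are not counted apart. For the counts and relations, 446 of 512 stayed within the limits set for them, 55 moved and 11 relations were no longer past the threshold. The 12 largest changes of MV-4-11, KG-1a, OCI-AML3 and Sig-M5 and the 20 of the average kept their calls under every alternative applied to single genes. In Kasumi-1 12 of 12, in NOMO-1 3 of 12 and in OCI-M1 2 of 12 lost it under at least 1 alternative.

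Some changes follow from how the alternative is built. A stricter threshold of 0.01 called 66 genes in Kasumi-1, 368 in NOMO-1, 345 in KG-1a, 114 in OCI-M1, 3231 in Sig-M5 and 2996 between lines. A minimum log2 fold change of 1 called 24 in Kasumi-1, 343 in MV-4-11, 109 in NOMO-1, 117 in KG-1a, 354 in OCI-AML3, 39 in OCI-M1, 649 in Sig-M5 and 51 on average. Testing every probe set, which counts probe sets, called 1443 in Kasumi-1, 2967 in MV-4-11, 1407 in NOMO-1, 1041 in KG-1a, 4421 in OCI-AML3, 491 in OCI-M1, 13094 in Sig-M5, 8351 on average and 12224 between lines.

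For the next alternatives the cause was not tested. Fitting each line alone, with its own variances and fewer residual degrees of freedom, called fewer genes with limma in Kasumi-1 (0, with 1728 at an unadjusted p under 0.05), MV-4-11 (904), NOMO-1 (202), OCI-M1 (63) and Sig-M5 (3575), and more in KG-1a (794) and OCI-AML3 (2368). Array weights, whose estimation did not converge, called 14 genes in Kasumi-1, 3252 in MV-4-11, 2587 in KG-1a, 5639 in OCI-AML3, 414 in OCI-M1 and 3255 in Sig-M5. The replicate block called 1934 in Kasumi-1 and 1002 in NOMO-1. Kasumi-1 had 308 calls with the mean of all probe sets, 932 with arrays centred on their median and 184 without tamibarotene replicate 1 and vehicle replicate 2, where 111 rose and 73 fell. The actin covariate called 28 in Kasumi-1, 1705 in Sig-M5 and 2306 on average. Without Sig-M5, 2221 genes were called on average and 2946 between lines, and without Kasumi-1 and Sig-M5 2728 between lines. Of the 248 list tests, 59 were called, 30 with an estimated correlation and 101 with fry, which tests another question.

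Leaving out each array in turn gave 15 to 1834 genes in Kasumi-1, 1117 to 1290 in MV-4-11, 399 to 984 in NOMO-1, 260 to 473 in KG-1a, 1705 to 1855 in OCI-AML3, 134 to 218 in OCI-M1, 2700 to 4728 in Sig-M5, 3025 to 3929 on average, 3923 to 5603 between lines and 51 to 63 lists. The lowest and highest counts of Kasumi-1 came without vehicle replicates 2 and 3, those of NOMO-1 without vehicle replicates 3 and 2, and the lowest of KG-1a and of Sig-M5 without vehicle replicate 2. Where 1 vehicle array is left, it is assumed to vary like the other groups.

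The relation of the RARA level to the number of called genes had r from 0.82 to 0.92 without single arrays. Its adjusted p rose above the threshold with array weights (r = 0.69), the actin covariate (0.76), the mean of the RARA probe sets (0.77) and the replicate block (0.81), and, with fewer lines, without Kasumi-1 (0.87), MV-4-11 (0.91), KG-1a (0.88), OCI-AML3 (0.88) or Sig-M5 (0.80).

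The changes of sign given here are those where the main or the alternative value was called. With the actin covariate the sign changed in Sig-M5 for ACTB (-0.04), HLA-E (-0.05), HOXB4 (0.13) and RNASE2 (-0.10). For HOXB4 it also changed without vehicle replicate 2 (0.02), whereas HOXB4 was at -1.17 without vehicle replicate 1. With the mean of all probe sets the sign changed for FLI1 (0.08) and RARB (0.20) on average, MSMO1 in Sig-M5 (0.53) and RARB in OCI-AML3 (0.93). ORM1 on average, a rise in Sig-M5, was at -0.06 without Sig-M5 and at -0.01 without Kasumi-1 and Sig-M5. The test of the secondary and tertiary granule proteins in OCI-M1 turned without the dimmest genes (adjusted p = 0.968). The cause of these changes of sign was not tested, apart from the line left out for ORM1.

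Correlations of same-numbered arrays across arms ran from -0.173 to 0.117 in Kasumi-1, 0.0995 to 0.67 in MV-4-11, 0.0105 to 0.572 in NOMO-1, -0.0721 to 0.0121 in KG-1a, -0.0425 to 0.461 in OCI-AML3 and -0.0448 to -0.0416 in Sig-M5. Array values near background limit the folds of genes that are dim in a group, and no fold there was tested against a background.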

Other observations

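The tests of the 13 lists described here were planned, and none was chosen after its result was seen.

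None of these 13 lists was called by camera in a line or on average. Of the 41 hematopoietic transcription factors, 8 rose and 9 fell on average (the same counts adjusted over the list alone), and the lowest adjusted p of the 8 contrasts was 0.157. ID1 rose by 4.04 in Sig-M5 and by 2.60 in MV-4-11, IRF4 by 2.27 in MV-4-11 and RUNX2 by 2.29 in Sig-M5, while GATA2 fell by 2.75 in MV-4-11 and KLF4 by 1.33 in OCI-AML3. Monocyte and macrophage markers moved both ways (6 rose and 7 fell of 24 on average, the same adjusted over the list alone, lowest adjusted p = 0.169). The scavenger receptor CD36 rose by 3.14 in Sig-M5, the cathepsins CTSD by 1.95 in OCI-AML3 and CTSB by 1.23 in MV-4-11, while CX3CR1 fell by 1.34 in MV-4-11 and the Fc receptor FCGR1A by 1.58 in OCI-AML3. Inflammatory cytokines and chemokines were split as well (5 rose and 5 fell of 27, the same adjusted over the list alone, lowest adjusted p = 0.208). CCL2 rose by 4.24 and CCL5 by 2.40 in MV-4-11, while TNF fell by 3.37 and VEGFA by 1.44 in Sig-M5.

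Of 23 stem and progenitor genes, 3 rose and 4 fell on average (the same adjusted over the list alone, lowest adjusted p = 0.648), with MN1 at 2.30 and SPINK2 at -1.19 in KG-1a and the receptor FLT3 at 2.01 in OCI-AML3. Of 18 immediate early and heat shock genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone, lowest adjusted p = 0.0738), and IER3 rose by 1.38 on average and by 2.19 in NOMO-1. B and plasma cell markers (2 rose and 1 fell of 15, the same adjusted over the list alone, lowest adjusted p = 0.0708) included IGLL1 at -2.16 in MV-4-11, VPREB1 at 1.69 in KG-1a and FCER2 at 1.71 in Sig-M5. Megakaryocyte and platelet markers (1 rose and 3 fell of 14, the same adjusted over the list alone, lowest adjusted p = 0.137) included PPBP at -2.07 in OCI-AML3 and F2RL3 at 1.85 in KG-1a. Erythroid markers (1 rose and 1 fell of 17, 1 and 0 adjusted over the list alone, lowest adjusted p = 0.119) included HEMGN at 1.08 in KG-1a.

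Of 10 measured HOX genes, 1 rose and 1 fell on average (the same adjusted over the list alone, lowest adjusted p = 0.119), with HOXB2 at 1.04 in KG-1a and HOXB6 at -0.97 in OCI-AML3. T and NK cell markers (1 rose and 1 fell of 20, the same adjusted over the list alone, lowest adjusted p = 0.114) included granzyme B, GZMB, at -0.92 in KG-1a. Markers of adherent cells (2 fell of 17, the same adjusted over the list alone, lowest adjusted p = 0.201) included VIM at -3.68 in Sig-M5 and -2.43 in MV-4-11. Chromatin and corepressor genes (2 rose and 4 fell of 18, the same adjusted over the list alone, lowest adjusted p = 0.279) included the histone methyltransferase SUV39H1 at -0.85 in Sig-M5. Common reference genes (2 rose and 1 fell of 13, the same adjusted over the list alone, lowest adjusted p = 0.0517) included GUSB, which rose by 1.04 in both MV-4-11 and OCI-AML3.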
